A study of Mus musculus with 6 samples.

How the data were processed

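RNA from mouse astrocytes of 2 brain regions was measured on 6 single-colour oligonucleotide arrays, 3 of neocortical and 3 of cerebellar astrocytes. Per the labels, the starting material was total RNA and the hybridised material was biotin-labelled amplified RNA. The ICR strain is named in the labels of the neocortical arrays alone. If the cerebellar arrays came from another strain, strain and region differed together, and no regional difference reported here could be told apart from one of strain. Whether samples of a group came from separate animals or preparations is not stated, so the p-values measure only the spread between these samples, which may be partly technical.

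The authors deposited 1 intensity value per probe set and array, on a linear scale with 1 decimal. The table holds 45101 probe sets, among them 64 control probe sets, with the identifiers of an Affymetrix mouse expression array. The summarisation method, its software and any detection calls are not given in the sources used here. The mean of the deposited intensities after trimming 2% at each end was 1500 on every array, as a global scaling per array would leave it. The medians ran from 284.7 to 361.2 and differed by up to 26.9%. No column belonged to a sample outside the series.

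The design fixed before the data were examined used the values as deposited only if the medians lay within 10% of each other. They did not, so the 45037 non-control probe sets were quantile normalized. Values under 62.2, the 20th percentile of all values, were raised to that floor, and log2 was taken. The 27022 probe sets whose mean over the 6 arrays was at or above the 40th percentile were tested. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 difference means higher signal in cerebellar astrocytes. Errors of differences are standard errors of the moderated fit, and means ± SD are of quantile-normalized signal. Signal is in arbitrary units, and levels of different genes were not tested against each other. Brightness was used only to choose a gene's probe set, to filter, and to choose which list members to name. Because no detection calls were used, 24 bacterial control probe sets (bioB, bioC, bioD, cre and dap) served as a description of the dim range. They read from 2.9 to 269.2, with a 95th percentile of 116. Folds are from the fitted log2 differences of floored values, so a fold with arrays at the floor is understated, and one against a group inside the dim range is uncertain. With every array of a group at the floor, the fold is a lower bound against the floor. Array number, at 3 per group, limits the precision.

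Gene names came from the platform annotation given with the series. It listed 1 symbol for 34945 of the analysed probe sets, several for 932 and none for 9160. Of the first, 34741 were found by Entrez ID in the GRCm38.p6 gene table, whose symbol was used. No coordinates are given, because the build behind the probe sets is not stated. Each gene was represented by its brightest probe set, which gave 12616 genes. Of the 107 named genes past the threshold, 54 had more than 1 probe set kept. All probe sets of a gene passed in the same direction for 28 of these, and none had a probe set that passed in the opposite direction. Among the rest, only 1 of 2 probe sets passed for Mecom, Wnt7a, Fzd5, Cxcl12, Cx3cl1, Fgf1, Egr3, Ptx3, Pfkfb3, Lss and Mcm6. For Gas1, Rsad2 and Tm4sf1 it was 1 of 3. For Efnb2 it was 2 of 4, and for Mbp 3 of 5.

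A total of 29 gene lists were fixed before the data were examined. The lists cover astrocyte markers, regional patterning genes, signalling pathways, secreted and matrix proteins, metabolism, and markers of other cell types. The 28 lists other than sex-linked genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. With an estimated correlation camera also uses far fewer degrees of freedom. A larger p value there therefore does not measure correlation between members alone. Genes were named by a rule also fixed beforehand. It took the 10 largest differences in each direction with no overlap between groups and no array at the floor. It added up to 5 genes per direction whose lower group lay at the floor on every array, and up to 4 members past the threshold in each list. Where under 2 members passed, the 2 brightest members were taken as well. Genes named outside that rule are marked as chosen after their values were seen.

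The arrays of the groups share the numbers 1 to 3. The deviations of same-numbered arrays from their group means correlated at 0.18, 0.188 and 0.101. Those of differently numbered arrays correlated at -0.182 to 0.0225. The arrays may thus be paired by number, which so few arrays do not settle. The main fit had no replicate block, as planned, so its p-values leave out any such pairing. The labels do not say what a number stands for. The fit with the replicate number as a block is reported where it changed a call. Alternatives comprised other scalings, floors, filters and thresholds, a fit without the variance trend, array weights, the replicate block, each array left out in turn, and the mean of a gene's probe sets. The exclusion of both arrays numbered 1 and of probe sets with a suffix was added after the data were seen, as was the correlation estimated per list under the alternatives that gave a list its call.

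The fit was tested on simulated arrays of this comparison, with 27022 probe sets tested and residual SDs smoothed by brightness. Of 50 probe sets changed per fold size, 44% were recovered at 1.5-fold, 82% at 2-fold, 94% at 4-fold and 98% at 8-fold. A further 20 probe sets were shifted by 0.6 on the log2 scale. Of the 176 probe sets called in that simulation, counting any of these 20, 7 were unchanged ones. Noise was drawn independently for each probe set, and far fewer probe sets were changed than the 2864 called in the real comparison. The recovered shares therefore need not hold for the real arrays.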

Results

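Gene expression was measured in astrocytes, the glial cells that support and surround neurons, from the neocortex and the cerebellum of mice. Each region was represented by 3 arrays, and the only comparison the design implies is between the regions. Spearman correlations of signal over all probe sets ran from 0.942 to 0.945 between neocortical arrays, from 0.932 to 0.938 between cerebellar arrays, and from 0.922 to 0.933 across regions. The ratio of 3′ to 5′ Gapdh control signal, a gauge of RNA integrity and labelling, was 0.996 ± 0.0795 (SD, n = 3) on cerebellar and 0.873 ± 0.00922 (SD, n = 3) on neocortical arrays, with every cerebellar array above every neocortical one. The two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. The actin ratio was 1.51 ± 0.102 against 1.4 ± 0.0462 (SD, n = 3 each), with an exact permutation p of 0.2.

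Transcription factors that pattern the brain along its length were among the genes with the largest fitted differences between astrocytes of the 2 regions. Lhx2, a homeodomain factor of the developing cortex, was 57.6-fold lower in cerebellar astrocytes, and Nr2e1, a forebrain nuclear receptor, was at least 51.3-fold lower. En2, the engrailed factor of the midbrain-hindbrain region, was 27.7-fold higher, and Pax3, a paired-box factor of the dorsal neural tube, was 46.5-fold higher with 1 neocortical array at the floor. The lower group's mean of each of these 4 genes lay in the dim range of the bacterial controls, so the sizes of their folds are uncertain. Over the whole array, 1319 probe sets were higher in cerebellar and 1545 were higher in neocortical astrocytes, together 10.6% of the 27022 tested. By brightest probe set, 669 genes were higher and 928 were lower in cerebellar astrocytes, of which 237 and 389 differed by at least 2-fold. The simulated fit recovered 44% of 1.5-fold changes, but with far fewer changed probe sets than were called here. Small differences may thus have been missed, in a share that the simulation does not fix. Scaling each array by its median in place of quantile normalization moved the counts to 819 higher and 2105 lower in cerebellar astrocytes, while the values as deposited gave 1586 higher and 1447 lower. Which region held the larger count thus depended on the scaling. Scaling by the median shifted the median of all probe sets from 0.009 to -0.096 on the log2 scale. Without neocortical replicate 1, 2 or 3 the counts were 589 and 737, 601 and 784, and 548 and 665, and without cerebellar replicate 3 they were 819 and 1121.

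The largest differences among genes with no array at the floor included several genes outside the patterning group. Iapp, the islet amyloid polypeptide, was 26.9-fold higher in cerebellar astrocytes, with a mean signal of 3032 against 115.9. Sned1 and Svep1, secreted or matrix proteins, were 11.6-fold and 7.81-fold higher. The sodium channel gene Scn7a was 9.78-fold higher, the secretogranin gene Scg2 9.15-fold, Pcp4l1 9.03-fold, Pgm5 8.43-fold and the zinc finger factor gene Mecom 7.58-fold higher. Myh8, a skeletal muscle myosin heavy chain gene, was at the floor on every neocortical array and at least 99.8-fold higher in cerebellar astrocytes (mean signal 6377, limma adjusted p = 6.49e-06). The transcript 5830408C22Rik was at least 10.8-fold higher by the same bound. Of genes higher in neocortical astrocytes, Fam107a was 16.2-fold higher (14550 ± 5580 against 860.5, SD, n = 3). Rgcc was 12-fold and Rgs7, a regulator of G protein signalling, 11-fold higher. The lower group's mean lay in the dim range, up to 269.2, for Iapp, Scg2, Mecom and Rgs7, so their folds are uncertain.

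Patterning genes divided by region. Of 18 measured midbrain-hindbrain and cerebellar genes, 12 were higher in cerebellar astrocytes, none was lower and 6 did not pass. Adjusted over the list alone, 15 were higher. Of 21 measured forebrain factors, 10 were lower in cerebellar astrocytes, 2 were higher and 9 did not pass, with 12 and 2 adjusted over the list alone. The iroquois genes Irx2 and Irx5 were higher, with log2 differences of 3.66 ± 0.191 and 2.83 ± 0.22 (SE). En2 had a mean signal of 5951 ± 1720 in cerebellar and 211 ± 28.7 in neocortical astrocytes (SD, n = 3 each, limma adjusted p = 1.6e-05). Lhx2 had 119.2 ± 39.3 and 6646 ± 421 (SD, n = 3 each, adjusted p = 7.42e-06). Dmrta2 was 26.2-fold, Emx2 21.4-fold, Otx1 13.5-fold and Otx2 12.1-fold lower in cerebellar astrocytes, with cerebellar means of 90.31 to 150.5 that lay in the dim range and 1 cerebellar array of Emx2 at the floor. The exceptions in the forebrain list, named after their values were seen, were Nr2f1 with a log2 difference of 0.94 and Zeb2 with 0.45. Zic1, on the hindbrain list, was bright in both groups, at 29750 ± 5800 in cerebellar and 11360 ± 1920 in neocortical astrocytes (SD, n = 3 each). The shift of the hindbrain list had a camera adjusted p of 1.18e-14 and that of the forebrain list 3.7e-06. With an estimated correlation, of 0.0597 for the hindbrain and 0.0146 for the forebrain list, the unadjusted camera p values were 0.00343 and 0.00768. The adjusted p values were 0.096 and 0.108. The forebrain estimate lay near the preset 0.01, so correlated members alone do not account for its weaker result. The median log2 difference was 1.73 for the hindbrain and -1.48 for the forebrain list. The forebrain median was -0.363 when the dimmest 60% of probe sets were left out, -0.504 with no filter and -0.706 with the floor at the 40th percentile, and the hindbrain median was 0.965 with no filter. The forebrain call was also lost with the first of these settings (adjusted p = 0.0873, with a range of 5.02e-07 to 0.0873 over 18 alternatives at the preset correlation).

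**Figure D1:**
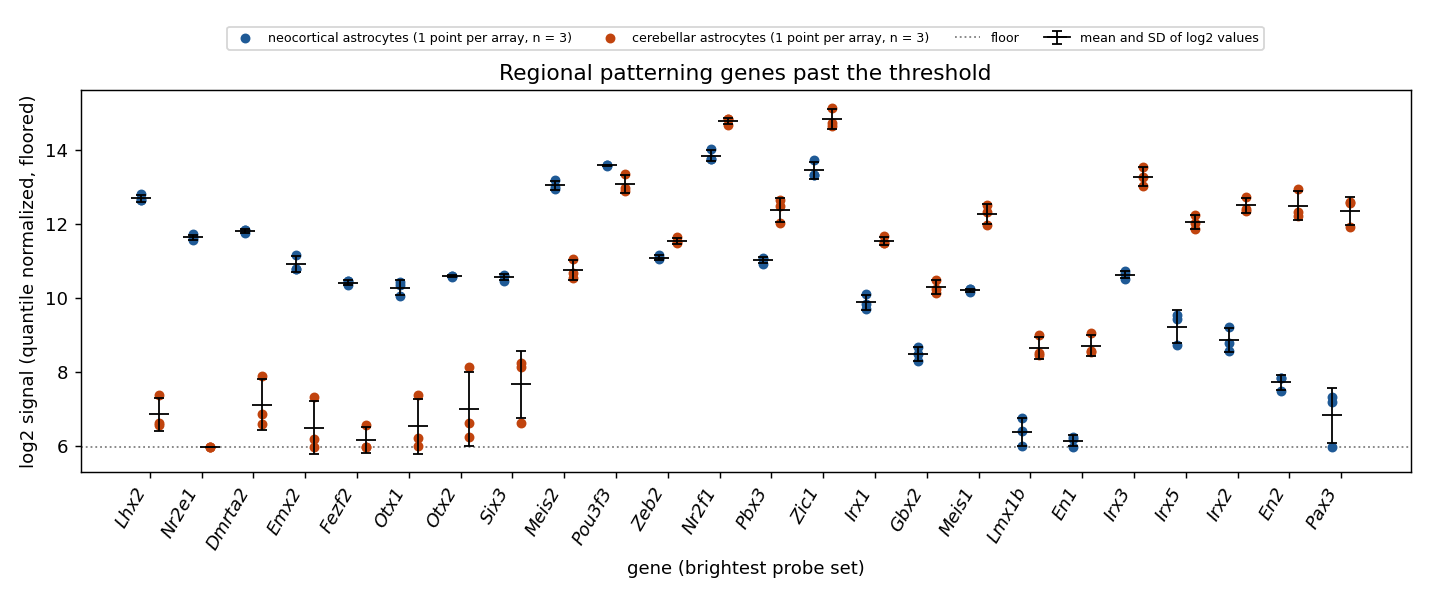
Log2 signal, quantile normalized with a floor at 62.2, of the regional patterning genes past an adjusted p of 0.05; each point is 1 array, bars show mean and SD of 3 arrays, and the dotted line is the floor. From Lhx2 to Pou3f3 the neocortical arrays lie higher, and from Zeb2 to Pax3 the cerebellar arrays lie higher.

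General astrocyte markers were on balance lower in cerebellar samples, and the list was mixed. Of 24 measured markers, 10 were lower, 1 was higher and 13 did not pass, with 12 and 2 adjusted over the list alone. The median log2 difference was -0.45, against -0.267 without cerebellar replicate 1 and -0.275 with the mean of a gene's probe sets. Ntsr2, a neurotensin receptor gene, was 13-fold lower (426.8 ± 167 against 5586 ± 2610, SD, n = 3). The fatty acid ligase gene Acsbg1 was 2.3-fold lower, glutamine synthetase (Glul) 1.76-fold and the glutamate transporter gene Slc1a3 1.75-fold lower, although only 1 of 6 probe sets of Slc1a3 passed. The water channel gene Aqp4, named after its value was seen, was the member that was higher, at 43870 against 28570 (adjusted p = 0.0434). Gfap, also named afterwards, had a log2 difference of -1.11 ± 0.329 (SE) and did not pass (adjusted p = 0.0649). The list's camera adjusted p was 0.00247, and the adjusted p was 0.6 with an estimated correlation. It was 0.063 when probe sets with a suffix were left out, and 0.000147 to 0.063 over 18 alternatives. Its median relative to the neocortical mean was -0.695, -0.222 and -0.334 on cerebellar arrays 1 to 3.

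Genes of glutamate, GABA and potassium handling were also lower on balance, with 11 of 29 lower in cerebellar astrocytes, 2 higher and 16 not past the threshold, and 15 and 4 adjusted over the list alone. Of the AMPA receptor subunit genes, Gria2 was 13.6-fold lower (163.6 ± 42.1 against 2192 ± 287), and Gria1 was 6.72-fold higher (16940 ± 2760 against 2539 ± 538, SD, n = 3 each). Gria4, named after its value was seen, was also higher, with a log2 difference of 1.325 ± 0.185 (SE). The cerebellar mean of Gria2 lay in the dim range. The potassium channel gene Kcnk1 was 4.22-fold lower and the metabotropic receptor gene Grm3 3.68-fold lower, the latter with a cerebellar mean in the dim range and 1 cerebellar array at the floor. Kcnj10, the inward rectifier of astrocytes, named after its value was seen, was lower, with a log2 difference of -1.66. The list's median was -0.57, against -0.33 without cerebellar replicate 1, -0.372 with both arrays numbered 1 left out and -0.356 with the mean of a gene's probe sets. It had a camera adjusted p of 0.0146 and an adjusted p of 0.71 with an estimated correlation. On cerebellar replicate 1 the list's median was -1.06, against -0.21 and -0.48 on the others, and without that array the adjusted p was 0.056, the highest of a range from 0.00184 over 18 alternatives.

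Markers of Bergmann glia, the radial astrocytes of the cerebellar cortex, did not pass as a list (camera adjusted p = 0.668), though 9 of 15 passed. A total of 6 were higher in cerebellar astrocytes, among them Gria1, the growth factor gene Gdf10 (6.29-fold) and the Wnt inhibitor gene Wif1 (4.16-fold), and 3 were lower, among them Septin4 (2.81-fold). Adjusted over the list alone the counts were 6 and 4. The median of this list was -0.08 while its mean was 0.41 and its tested direction was upward. Relative to the neocortical mean, the list's median was 0.213, 0.0336 and -0.317 on cerebellar arrays 1 to 3, so its sign differed between arrays.

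Of the Wnt genes, 7 of 24 were lower and 5 were higher in cerebellar astrocytes, with 9 and 5 adjusted over the list alone. The ligand gene Wnt7a was 12.9-fold, Rspo3 7.54-fold and the receptor gene Fzd5 4.9-fold lower, and Wif1 was higher. The cerebellar means of Wnt7a and Rspo3 lay in the dim range. In the Notch list 4 of 17 were lower and none was higher, with 6 and 0 adjusted over the list alone. These were the effector genes Hes5 (6.53-fold) and Hey2 (3.89-fold), the ligand gene Dll1 (3.39-fold) and the feedback regulator gene Nrarp (2.07-fold), with cerebellar means for the first 3 of 69.97 to 162.8 that lay in the dim range and 2 cerebellar arrays of Hes5 at the floor. The Notch list had a camera adjusted p of 0.0652, which became 0.0466 with the replicate block (range 0.0343 to 0.603 over 18 alternatives). With an estimated correlation the adjusted p was 0.546, and 0.561 with the replicate block. The Wnt list did not pass (adjusted p = 0.179).

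Of 15 Sonic hedgehog genes, Hhip (2.61-fold) and Boc (1.92-fold) were higher and Gas1 (1.38-fold) was lower in cerebellar astrocytes, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.668). Of 26 BMP and TGF-beta genes, 6 were lower and 2 were higher, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.696). The lower ones included Bmpr1b (2.47-fold), Bambi (2.34-fold), Tgfb2 (1.73-fold) and Nog (1.81-fold), and Nog did not pass with the replicate block (adjusted p = 0.0527, range 0.0258 to 0.145 over 17 alternatives). Of 36 growth factor genes, 7 were lower and 3 were higher, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.997). The median of this list was 0.10 while its mean was -0.06 and its tested direction was downward, which turned upward with the replicate block (adjusted p = 0.994, range 0.752 to 0.997 over 18 alternatives). Of insulin-like growth factor binding proteins, Igfbp4 was 6.09-fold higher (32420 ± 2840 against 5334 ± 667, SD, n = 3), while Igfbp3 was 2.67-fold and Igfbp5 2.3-fold lower, and Fgf1 was 3.61-fold lower. Of 33 cAMP signalling genes, 4 were lower and 3 were higher, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.843). These included 4 phosphodiesterases, of which Pde7b (2.07-fold) and Pde3b (2.05-fold) were higher and Pde4b (1.85-fold) and Pde1a (1.84-fold) lower.

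Matrix genes changed in both directions. Of 38 extracellular matrix genes, 9 were higher and 5 were lower in cerebellar astrocytes, with 12 and 8 adjusted over the list alone. Fbln2 (fibulin 2) was 3.53-fold and the basement membrane gene Nid1 3.26-fold higher, while the collagen gene Col11a1 was 3.47-fold and the neural proteoglycan gene Ncan 3.22-fold lower. The median log2 difference of the whole list was 0.374, against 0.117 without cerebellar replicate 3. The list did not pass (camera adjusted p = 0.12), passed with the replicate block (0.0184), and had an adjusted p of 0.824 with an estimated correlation, 0.667 with the block. Fibroblast markers were likewise lowest on cerebellar replicate 1 and highest on cerebellar replicate 3 of the 3 cerebellar arrays. Without cerebellar replicate 1 the camera adjusted p of the matrix list was 0.00356, in a range of 0.00202 to 0.55 over 18 alternatives. With an estimated correlation it was 0.763 without that array. The median of the matrix genes relative to the neocortical mean was -0.134, 0.321 and 0.736 on cerebellar arrays 1 to 3, and 11 of the 38 are also on another list. Of 16 synapse-organising proteins, some secreted and some on the cell membrane, 5 were higher and 5 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.82, with a median of -0.03, a mean of 0.05 and an upward tested direction). The thrombospondin gene Thbs2 was 3.32-fold higher and Thbs1 2.71-fold lower. Sparcl1 (hevin) was 3.23-fold higher, and the membrane protein gene Nlgn1 2.56-fold lower with a cerebellar mean in the dim range. Of 40 guidance genes 4 were lower and 4 higher, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.878). They included netrin 4 (Ntn4), 5.34-fold lower, and Unc5c (3.14-fold), Plxna2 (2.45-fold) and Efnb2 (1.77-fold), all higher.

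The chemokine Cxcl12 and its receptor Cxcr4 were both higher in cerebellar astrocytes, by 2.76-fold and 2.3-fold, as were Cxcl5 (2.52-fold, with a neocortical mean in the dim range) and Cx3cl1 (2.49-fold). Of 26 chemokine and cytokine genes 7 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.104, 0.0182 without cerebellar replicate 1, range 0.0154 to 0.271 over 18 alternatives). With an estimated correlation the adjusted p was 0.546, and 0.672 without that array. The list's median of 0.11 became 0.292 without cerebellar replicate 1, and -0.07 when arrays were scaled by the median. Under that scaling its camera test was upward and passed (adjusted p = 0.0313, and 0.75 with an estimated correlation). Of 35 reactive astrocyte genes, 6 were higher and 3 were lower, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.316). Timp1 (3.1-fold), Ptx3 (1.68-fold) and Tm4sf1 (1.64-fold) were higher and the serpin gene Serpina3n was 3.27-fold lower. Of 21 interferon-stimulated genes, Gbp3 (2.08-fold) and Rsad2 (1.91-fold) were lower and none was higher, with 4 and 0 adjusted over the list alone (camera adjusted p = 0.179, 0.02 without cerebellar replicate 3, range 0.02 to 0.829 over 18 alternatives). With an estimated correlation the adjusted p was 0.824, and 0.678 without that array.

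The immediate early genes Egr3 (4.62-fold), Egr2 (2.64-fold) and Ier2 (2.44-fold) were higher in cerebellar astrocytes, while Fosb was 1.68-fold lower. Of the 23 immediate early and heat shock genes, 8 were higher and 2 were lower, with 10 and 3 adjusted over the list alone. The list's camera adjusted p was 0.0275, and the adjusted p was 0.546 with an estimated correlation. Without neocortical replicate 1 the adjusted p was 0.0582, in a range of 0.0053 to 0.0711 over 18 alternatives. The list's median of 0.27 was 0.0456 when arrays were scaled by the median and 0.075 with both arrays numbered 1 left out. Of 25 glycolysis and hypoxia genes, 9 were lower and 3 were higher, with 11 and 3 adjusted over the list alone (camera adjusted p = 0.139). The kinase genes Pdk1 (2.12-fold) and Pfkfb3 (1.76-fold) and the monocarboxylate transporter gene Slc16a1 (1.74-fold) were lower, and the glucose transporter gene Slc2a3 was 2.04-fold higher. Of 21 cholesterol genes, Lss (1.55-fold) and Fdft1 (1.39-fold) were lower and Sqle, a rate-controlling enzyme of the pathway, was 2.16-fold higher, with 7 and 1 adjusted over the list alone. Lss did not pass with the replicate block (adjusted p = 0.0652, range 0.0197 to 0.254 over 18 alternatives). The cholesterol list had a camera adjusted p of 0.0415 and an adjusted p of 0.546 with an estimated correlation. It lost its call without either neocortical replicate 1 or 2 or cerebellar replicate 2 or 3 (0.0521 to 0.103), and passed under 10 of 18 alternatives (range 0.00457 to 0.103).

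Of 32 measured proliferation genes, Mcm6 was 1.4-fold higher and 31 did not pass, with none past the threshold by limma adjusted over the list alone, and 4 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.668). Pcna read 36120 ± 1730 in cerebellar and 36910 ± 2940 in neocortical astrocytes, and Mcm7 read 11480 ± 134 and 9437 ± 1140 (SD, n = 3 each). The quartiles of the list's log2 differences were -0.12 and 0.11, and its median of 0.03 became -0.10 when arrays were scaled by the median.

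**Figure D2:**
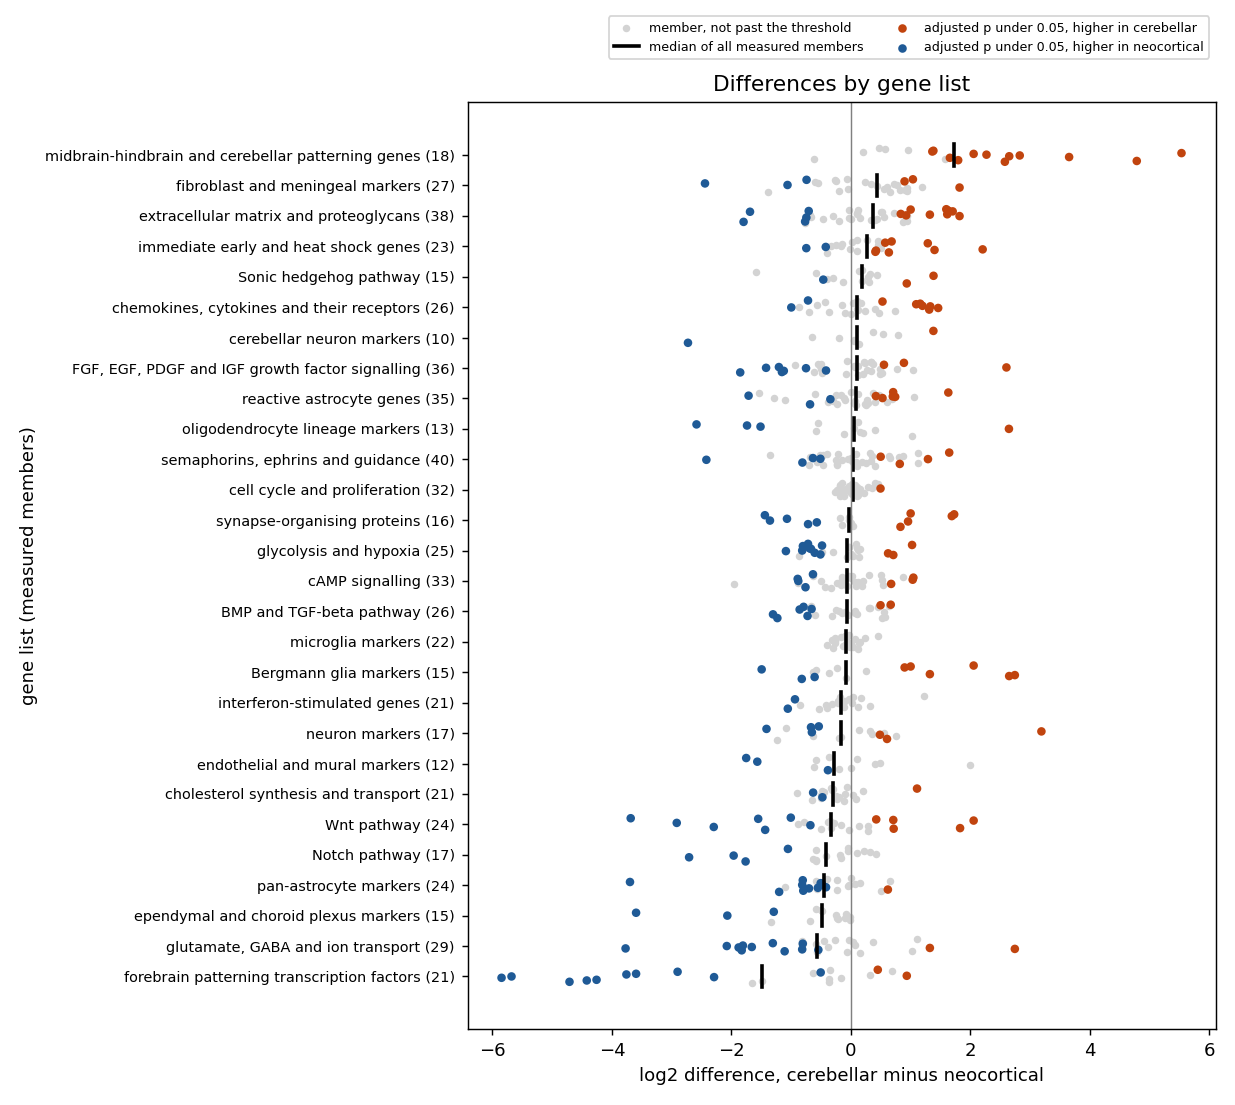
Log2 difference, cerebellar minus neocortical, of every measured member of 28 gene lists (1 point per gene), with orange and blue for members past an adjusted p of 0.05 and a black bar at each list's median. The hindbrain list has its median at 1.73 and the forebrain list at -1.48, while the median of the proliferation list is 0.03.

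Markers of cell types other than astrocytes were measured in both groups. None of 22 microglia markers passed by limma, over all genes, adjusted over the list alone, or at an unadjusted p under 0.05 (camera adjusted p = 0.997), and the brightest, Lyz1 and Csf1r, had log2 differences of 0.06 ± 0.694 and 0.00 ± 0.584 (SE). The spread between arrays was wide. Microglia markers had medians of -1.45, 0.723 and 0.278 relative to the neocortical mean on cerebellar arrays 1 to 3, and of -0.0761, 0.716 and -0.663 on neocortical arrays 1 to 3. Without cerebellar replicate 1 the microglia list was higher in cerebellar astrocytes (camera adjusted p = 0.00457, range 0.00457 to 0.997 over 18 alternatives). That call was not kept with an estimated correlation, where the adjusted p was 0.8 without that array and 0.999 with all arrays. Fibroblast and meningeal markers had medians of -0.909, 0.374 and 1.28 on the cerebellar arrays and between -0.158 and 0.291 on the neocortical ones. Of 27 measured, 3 were higher, among them Fbln2 and the mesenchymal factor gene Twist1 (2.06-fold), and 3 were lower, among them Ogn (5.43-fold) and Islr (2.08-fold), with 4 and 4 adjusted over the list alone. The list did not pass (camera adjusted p = 0.443) and did so without cerebellar replicate 1 (0.00231, range 0.00223 to 0.653 over 18 alternatives). With an estimated correlation the adjusted p was 0.742 without that array and 0.824 with all arrays. Its median was 0.445, and was 0.92 without cerebellar replicate 1 and -0.15 without cerebellar replicate 3, and 11 of the 27 markers are also on another list.

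Of 13 measured genes of the oligodendrocyte lineage, Olig2 (5.99-fold), Olig1 (3.33-fold) and Nkx2-2 (2.85-fold) were lower and Mbp, a myelin gene, was 6.27-fold higher at a mean signal of 991 ± 228 (SD, n = 3), a neocortical mean in the dim range and 1 neocortical array at the floor, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.668). The median of this list was 0.06, its mean -0.19 and its tested direction downward. Of 17 neuron markers 4 were lower, among them Stmn3 (2.66-fold, with a cerebellar mean in the dim range), Syt1 (1.59-fold) and Rtn1 (1.57-fold), and 3 were higher, among them Scg2, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.843). Of 10 cerebellar neuron markers Zic1 was 2.61-fold higher and Car8 6.61-fold lower with a cerebellar mean in the dim range and 1 cerebellar array at the floor, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.668). The median of this list was 0.10, its mean -0.03 and its tested direction upward. Of 12 endothelial and mural markers Slco1a4 (3.36-fold), Kdr (2.96-fold) and Acta2 (1.3-fold) were lower, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.179). With the filter at the 60th percentile the list passed, at a median of -0.485 against -0.285 (adjusted p = 0.0227, range 0.0227 to 0.493 over 18 alternatives). With an estimated correlation the adjusted p was 0.58 under that filter and 0.546 under the filter used. Of 15 ependymal and choroid plexus markers Otx2, Folr1 (4.19-fold) and Rarres2 (2.44-fold) were lower, also adjusted over the list alone. That list's median was -0.477, against -0.0614 without cerebellar replicate 1, -0.219 without neocortical replicate 2 and -0.717 without cerebellar replicate 2. It was -0.104 with both arrays numbered 1 left out, -0.2 with array weights and -0.235 with no filter. The list had a camera adjusted p of 0.0446 and an adjusted p of 0.717 with an estimated correlation. It lost its call without cerebellar replicate 1 (0.35), on which its median was -1.3, or neocortical replicate 2 (0.235), and passed under 10 of 18 alternatives (range 0.00298 to 0.35).

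**Figure D3:**
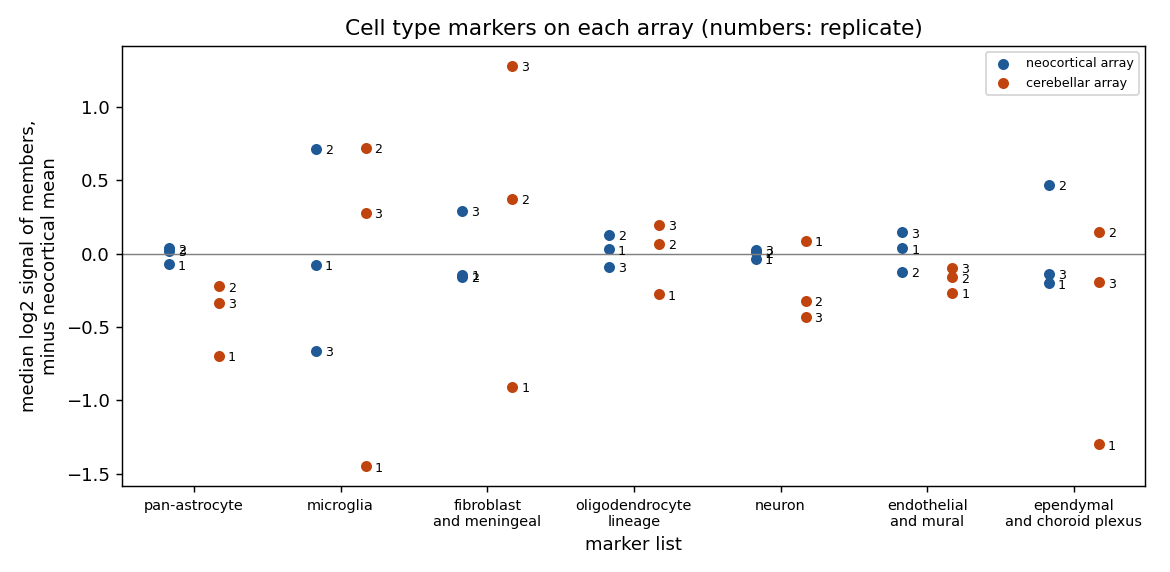
Median log2 signal of the members of 7 cell type lists on each array, minus the neocortical mean of each gene; numbers mark the replicate. Cerebellar array 1 is lowest for every list but neuron markers, among them microglia (-1.45), fibroblast (-0.909), ependymal (-1.3) and astrocyte markers (-0.695). All cerebellar arrays lie below the neocortical ones for astrocyte markers.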

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

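The bacterial spike-in probe sets for lys, phe, thr and trpn, 21 in all and outside the comparison, gave signal on every array. Their values ran from 790.9 to 79967.2 over all these probe sets and arrays together. Their median log2 difference, cerebellar minus neocortical, was 0.0686 as deposited, 0.0637 after quantile normalization and -0.0971 after scaling by the median.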

How the results depend on the processing

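The exclusion of both arrays numbered 1 and of probe sets with a suffix was chosen after seeing the data. Counts of probe sets higher in cerebellar and in neocortical astrocytes, 1319 and 1545, were 577 and 704 with no filter on dim probe sets, where more are tested, 676 and 914 with no variance trend, and 819 higher in cerebellar with each array scaled by its median. They were 580 and 737 with both arrays numbered 1 left out, 502 and 691 at 2-fold or more, and 410 and 585 at an adjusted p under 0.01. With 1 array left out they ran from 548 to 1233 and from 665 to 1542, with fewer samples in the fit. The replicate block gave 1557 and 1785. It changed the calls of the Notch and matrix lists and of Nog and Lss, and no other call of a list or of a gene named by the rule fixed beforehand. Genes named after their values were seen are not covered by this. Of 28 lists, 7 were called, against 4 with the filter at the 60th percentile, 3 with only probe sets with no suffix, 0 with the correlation estimated per list and 9 with the replicate block. Of 107 named genes past the threshold, 66 had a value under every alternative, of which 40 kept their call and direction wherever all 6 arrays were used and 38 also with arrays left out. The other 41 lacked a value somewhere, 22 with the filter at the 60th percentile and 23 with no suffix. With no filter, 46 of the 107 lost their call.

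Reversals of direction, by the sign of the test, were in lists and genes that had not passed, and except where the array is named the cause was not tested. With each array scaled by its median, list medians were -0.175 for cAMP signalling, -0.104 for cell cycle, -0.0617 for growth factors, -0.198 for microglia, 0.0596 for oligodendrocyte and -0.156 for neuron markers, and log2 differences were -0.1651 for Lyz1 and -0.2134 for Csf1r. With no suffix they were -0.0339 for synapse organisers and 0.0283 for cAMP signalling. With no filter guidance genes had 0.0106. Growth factors had 0.0964 with the replicate block and 0.119 with the mean of a gene's probe sets. Microglia markers had -0.0453 with the floor at the 40th percentile, 0.106 with array weights, 0.474 with both arrays numbered 1 left out and -0.0756 with the mean of a gene's probe sets. Pcna was 0.004654 as deposited and 0.03997 with both arrays numbered 1 left out. Csf1r was -0.04687 as deposited and -0.03658 with the mean of its probe sets. With 1 array left out, medians ran from -0.0172 to 0.0808 for cell cycle, 0.00802 to 0.148 for growth factors, -0.551 to 0.544 for microglia and -0.15 to 0.921 for fibroblast markers, and log2 differences from -0.09412 to 0.01903 for Pcna, -0.5404 to 0.9002 for Lyz1 and -0.5091 to 0.738 for Csf1r. Genes whose signal lies within the range of the bacterial controls, up to 269.2, are limited by that background.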

Other observations

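The tests of explanations in this part were chosen after the results were seen, while the fits with 1 array left out were planned.

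Sex-linked genes differed between arrays of the same region. Xist, the RNA that silences an X chromosome in female cells, had a signal of 203.7, 26485.8 and 25816.3 on neocortical arrays 1 to 3 and of 199.4, 32131.9 and 35589.4 on cerebellar arrays 1 to 3. The Y-linked gene Kdm5d read 1812.9, 61.5 and 55.4, and 1620.2, 54.1 and 9.6, in the same order. Eif2s3y read 2591.6, 76.7 and 64, and 3123.6, 9.7 and 32, and Uty read 952.8, 78.9 and 77.3, and 1236.8, 115.5 and 37.9. With these values, array 1 of each region was not a repeat measurement of the same RNA as its arrays 2 and 3, so part of the spread within each region was not technical. Whether arrays 2 and 3 of a region came from separate animals is not settled by these genes. On array 1 of each region Xist was low and the Y-linked genes were high, the reverse of its arrays 2 and 3. Leaving out any 1 array therefore gave the regions unequal shares of arrays with each pattern, which limits the results without cerebellar replicate 1.

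The 2864 probe sets called between the regions were set against other splits of the 6 arrays. Of 10 splits, 1, the real one, gave as many, and the highest of the others gave 0. The splits are too few for a share under 0.05. Every other split also put arrays of both regions on each side. Differences between the regions then added to the spread within each side and lowered its count. The contrast therefore does not show what groups without a regional difference would give. The other splits that part all 3 same-numbered pairs also gave 0.

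Of 24 astrocyte markers 10 were lower in cerebellar samples, 1 was higher and 13 did not pass, with a list adjusted p of 0.00247 that became 0.6 with an estimated correlation, and a lower share of astrocytes in the cerebellar samples was weighed as an explanation. Such a change would lower alike only markers confined to astrocytes, and raise those of other cell types. The 95% interval left out the list median for 10 of 24 markers, and for 14 without cerebellar replicate 1. The markers thus did not shift alike. This does not decide the matter, because the list is not restricted to genes found only in astrocytes. One member that left out the median, Vim, was held at 145500 in both groups by quantile normalization. The other cell types do not settle it either: of their 105 markers 7 were higher and 16 lower, but the fibroblast list had a median of 0.445. Without cerebellar replicate 1 the medians were 0.921 for fibroblast, 0.544 for microglia and -0.267 for astrocyte markers. Without that array the fibroblast and microglia camera adjusted p values were 0.742 and 0.8 with an estimated correlation. Beside a change in share, a regional difference in marker expression may remain. Neither it nor a strain difference, if there was one, was tested apart from the regions.

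The 9 matrix genes called higher in cerebellar samples had a median log2 difference of 1.6, which is high because they were chosen by that call. The whole list of 38 had a median of 0.374, and of 0.117 without cerebellar replicate 3. More fibroblasts or meningeal cells in the cerebellar samples may be a cause of higher matrix signal. On cerebellar replicate 1, which had the lowest fibroblast markers, the 31 matrix genes outside the fibroblast list had a median of -0.072 relative to the neocortical mean, below the highest neocortical array at 0.203. Of 20 fibroblast markers outside the matrix list, 2 were higher and 3 lower. Of the 5 brightest markers of the whole list, Ogn was lower (6600 in cerebellar against 34370 in neocortical samples), and Col3a1 (49710 against 18950), Col1a2 (24600 against 23450), Col1a1 (25870 against 14130) and Dcn (18170 against 8727), all also matrix genes and named after their values were seen, did not pass by limma. The matrix median and the counts outside the matrix list point in opposite directions and the first rests on 1 array, so such cells and a regional difference cannot be told apart for these genes.

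Of 16 immediate early genes 7 were higher in cerebellar samples and 1 lower, and a general stress response could be a cause. Fos and Jun, named after their values were seen, were among those that did not pass by limma (log2 differences of -0.008 and 0.027). The 7 heat shock genes had a median log2 difference of -0.164, with a resampled 95% interval of -0.323 to 0.413 and 1 gene past the threshold each way. Both ends of the interval are log2 differences of single heat shock genes. It thus describes the spread between these genes and not between arrays. The interval holds 0.219, 50% of the immediate early median of 0.439, so the heat shock genes do not decide it. A response to handling without heat shock genes, and a regional difference, were not tested.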
